A study of Mus musculus with 150 samples.

How the data were processed

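Smart-seq libraries of 150 single mouse neurons were used, 1 cell per sample. Per the labels, polyA RNA was taken from CD1 mice of Charles River, cDNA was made in 5 batches, and libraries were made with Nextera XT. FastQC, cutadapt, Salmon and the mm10 genome were used per the submitters' processing notes. Their versions, the annotation and the step from transcripts to genes are not given in the sources used here. The deposited table holds Salmon expected counts per gene and cell as whole numbers, not normalized between cells, for 54082 genes, of which 19341 had no count in any cell. Whether the authors scaled these expected counts for transcript length is not given in the sources used here. Across protein-coding genes with a mean of at least 1, the Spearman correlation of mean count with gene length was 0.007 for the union of exons (13176 genes), -0.145 for the median transcript (13158 genes) and -0.076 for the longest. These are correlations across genes, and genes are not independent replicates. A fold change of 1 gene between groups keeps its meaning either way, whereas levels of different genes may not be on 1 scale. Gene symbols are those of the table, and positions come from a GENCODE annotation of mm10.

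Each cell was checked for total counts, detected genes, and mitochondrial and haemoglobin share. A minimum of 2000 detected genes removed 0 cells. The 6 cells under 10000 detected genes stayed in and were left out as an alternative. No pair of cells had identical counts, and the highest correlation of a pair was 0.933. Cells were clustered without reference to skin type with scanpy 1.11.5 (2000 variable genes among those seen in at least 3 cells, 20 principal components, 10 neighbours, Leiden resolution 1, igraph 0.11.9, seed 0). A cluster took the name of a neuron class when at least 3 of the class's markers were enriched by a log2 of more than 1 and detected in at least 50% of its cells, with a margin of 2 over the next neuron class. Markers of non-neuronal cells did not enter this rule.

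The litter was the replicate. Counts were summed per litter and skin type, with at least 2 cells of each skin type in a litter, which left 7 of 10 litters. The cell labelled with both skin types was in no comparison. Sums were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM normalization, filterByExpr, and quasi-likelihood F-tests with the litter as a block, at a Benjamini-Hochberg adjusted p of 0.05. The SE of a log2 change is its size divided by the square root of F. CPM values (counts scaled to the library total) use totals scaled by TMM in the test and raw totals in the means. Mean levels are given with their SD over litters. The block takes up age, plate and cDNA batch except in litter K, whose cells lay on both plates. Correlations between the glabrous and the hairy sum of a litter, after centring each gene within its skin type, were -0.024 (C_D), 0.094 (E_F_G), 0.261 (H), 0.265 (K), -0.08 (L), 0.075 (O) and 0.182 (P_Q), and 4 of 7 hairy sums correlated best with their own litter. For A-fibre and peptidergic neurons the planned minimum of 2 cells left fewer than 3 litters, and at least 3 had been planned for a test. Sums of at least 1 cell were used instead, a change from the plan made after the data had been seen. Age was tested between litters in glabrous cells (in hairy cells as an alternative), and its interaction with skin type in the paired litters.

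Named genes were fixed by rule before the data were examined: the 12 largest changes per direction among genes that passed with at most 1 litter in the other direction, the 10 smallest p-values where fewer than 10 passed, 2 to 4 members of each list described, and 14 fixed genes of touch and BMP signalling. The 28 gene lists (381 entries) and the marker lists were also fixed before the data were examined. Lists with at least 3 measured members were tested with camera (preset correlation 0.01, and with an estimated correlation) and with fry, which left 24 lists over all neurons and 23 in A-fibre neurons. Markers of somatostatin pruriceptors, cold-sensing neurons, endothelium and macrophages had fewer than 3 measured members in both. Class shares, detected genes and markers of other cell types were compared with exact two-sided sign-flip permutation tests over the 7 paired litters. Shares of pooled cells have exact Clopper-Pearson 95% intervals, and a count of 0 is read as allowing 3. Software also included Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and DESeq2 1.42.0.

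The procedure was tested on simulated data, negative binomial counts drawn from the fitted means and dispersions of the same sums without their skin or age effect, with changes added to 200 genes. Over all neurons edgeR recovered 33.3% of changes of 1 log2 unit, 75% of 2 and 93.9% of 3, with 1 false call among 148. For A-fibre neurons it recovered 13.6%, 79.2% and 95.7%, with 2 false calls among 139, and for age 4.2%, 46.8% and 81.2%, with 6 among 116. Genes were drawn independently, with 1 dispersion per gene for all sums, whereas the real sums over all neurons held from 2 to 31 cells. The simulation therefore cannot show how many calls are false in the real data. Alternatives covered normalization, the low-count filter, DESeq2, voomLmFit with sample weights, limma on mean log2(CPM + 1), cells as units, no litter block, other minimum cell numbers, day 5 only, each plate, and leaving out each litter. Alternatives chosen after seeing the data were plate 1 alone (and plate 2 for class shares), cells with at least 10000 detected genes, sums without C-fibre-like cells, the cluster as a covariate (with edgeR, and with voomLmFit and each litter and skin type as a random block), the level of non-neuronal markers as a covariate, thinning of counts to 395811 per cell, detected genes compared within litter and cluster, clustering without 391 genes whose mean differed in the same direction in all 7 litters by more than 0.5 on average (log2, not a test) or without 779 that follow non-neuronal markers (Spearman correlation above 0.4), and the comparisons within clusters.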

Results

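RNA of 150 single somatosensory neurons from early postnatal CD1 mice was sequenced by Smart-seq, a method that copies whole polyA transcripts of a single cell. Each sample was 1 cell, labelled by the skin its neuron innervated: 45 cells were hairy, 1 carried both labels and all others were glabrous (hairless skin). How a neuron was assigned to a skin type is not given in the sources used here. The cells came from 10 litters, 33 cells at postnatal day 4 and all others at postnatal day 5, and were processed on 2 plates. Plate 1 held 85 glabrous and 10 hairy cells, and plate 2 held 19 glabrous and 35 hairy cells. Total counts per cell ran from 395811 to 1053854, with a median of 761491.5 in glabrous and 703718 in hairy cells. The number of detected genes per cell ran from 4360 to 15865, with a median of 14183.5. The litter was the replicate throughout, and 7 litters held at least 2 cells of each skin type. Litter names that join letters, such as C_D and E_F_G, were each taken as 1 litter, as labelled.

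The neurons fell into 8 expression clusters, and marker lists of known sensory neuron classes named 6 of them. Clusters 3, 5 and 7 resembled A-fibre low-threshold mechanoreceptors, the myelinated neurons of light touch. The neurofilament gene Nefh had a median of 2043 CPM (counts scaled to the library total) in cluster 3, 1762 in cluster 5 and 1229 in cluster 7. Cluster 3 also expressed the GDNF receptor gene Ret, at a median of 638 CPM, and the transcription factor gene Mafa, at 18.1. Cluster 5 had the highest median of the neurotrophin-3 receptor gene Ntrk3, 508 CPM, and cluster 7 the highest median of the BDNF receptor gene Ntrk2, 467. Beside 9, 6 and 8 markers of the A-fibre class, clusters 3, 5 and 7 were enriched for 3, 3 and 2 markers of proprioceptors. One of these, Runx3, was enriched in cluster 5 only, with a median of 60.3 CPM there. Cluster 6 resembled C-fibre low-threshold mechanoreceptors, unmyelinated touch neurons, with medians of 882 CPM for Tafa4, which encodes a secreted chemokine-like protein, and 206 for the zinc-finger gene Zfp521. The median of Th, another marker of that class, was 4.46 CPM there. Clusters 1 and 8 resembled peptidergic nociceptors, with Calca, the gene of the neuropeptide CGRP, at medians of 1472 and 2473 CPM. Cluster 2, with a median of 1886 CPM for Nefh, and cluster 4, with Calca and Mrgprd at medians of 1884 and 756, were not named. Markers of myelinating Schwann cells and fibroblasts were highest in clusters 6 and 8. Their summed medians were 5343 and 1118 CPM in cluster 6, and 4639 and 1644 in cluster 8. Satellite glia markers were also highest in cluster 8, at 3597 CPM.

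The design asks whether the 2 skin types are served by the same mix of neurons. C-fibre low-threshold mechanoreceptor-like cells made up 25.95% ± 22.8 (SD, n = 7 litters) of hairy-skin neurons and 4.76% ± 12.6 of glabrous-skin neurons. The difference of 21.2 percentage points was positive in 5 litters and 0 in 2. Over all cells the class held 14 of 45 hairy cells (31.1%, exact 95% interval 18.2 to 46.6) and 3 glabrous cells (2.88%, 0.599 to 8.20). A-fibre low-threshold mechanoreceptor-like cells made up 33.3% ± 36.1 of hairy and 43.6% ± 18.5 of glabrous neurons, and peptidergic nociceptor-like cells 24.05% ± 21.3 and 20.5% ± 14.9. Cluster 2 held 20 glabrous cells and cluster 5 held 17. Neither held any of the 45 hairy cells, which allows a share of up to 6.67%, and all such intervals and limits cover counting error only.

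Class shares were compared with an exact two-sided sign-flip test over the 7 litters, where a litter with a difference of 0 raises the smallest p that can be reached. For the C-fibre class that test gave p = 0.0625, the smallest possible with 2 such litters, so it could not pass (Benjamini-Hochberg adjusted p = 0.312, a difference of 21.2 points, higher in hairy skin in 5 of 7 litters and lower in 0). Without any 1 litter the difference ran from 16.4 (without O) to 24.7 points (without C_D or H), and with at least 1 cell of each skin type it was 10.1 ± 30.2 points in 9 litters. For cluster 2 the exact test gave p = 0.125, again the smallest possible (adjusted p = 0.312, a difference of -17.1 points, lower in 4 of 7 litters and higher in 0). For the A-fibre class, with no litter at 0, it gave p = 0.594 (adjusted p = 0.812, -10.2 points, lower in 4 of 7), and the difference ran from -26.5 without litter C_D to -0.84 without litter L. Taken over the 8 clusters, cluster 5 had an exact p = 0.0625, the smallest possible (adjusted p = 0.25, -19.7 points, lower in 5 of 7 litters and higher in 0). Within plate 1 the C-fibre difference was 6.67 ± 11.5 points (SD, n = 3 litters), positive in 1 litter and 0 in 2, so the exact test could only give 1.00. Within plate 2 it was 32.1 ± 11.97 points (n = 4 litters), positive in all 4, with an exact p of 0.125, the smallest possible.

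**Figure D1:**
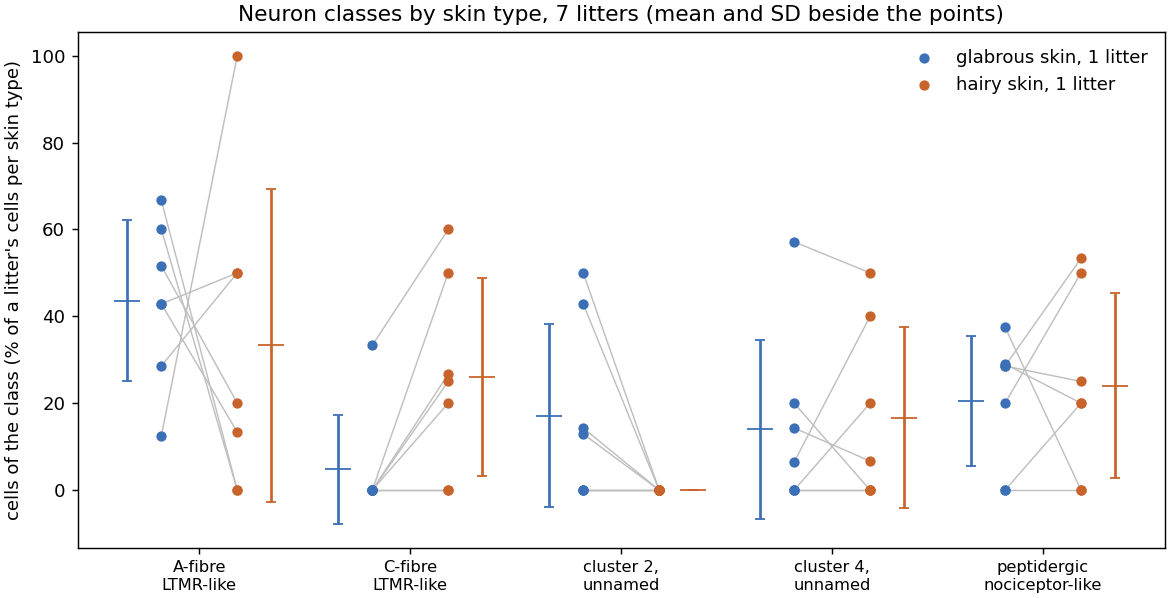
Share of each neuron class (% of a litter's cells of 1 skin type, y axis) in glabrous and hairy skin for 7 litters, where points are litters, lines join the same litter, and bars beside them show mean and SD. C-fibre low-threshold mechanoreceptor-like cells averaged 25.95% in hairy and 4.76% in glabrous skin, and cluster 2 held no hairy cell.

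Over all neurons, hairy-skin neurons had far less Uts2b, which encodes the peptide urotensin-2B, and less Cntn5, which encodes a contactin adhesion molecule. Uts2b averaged 63.7 ± 13.4 CPM in glabrous and 1.85 ± 1.74 in hairy sums (SD, n = 7 litters), a log2 change of -5.26 ± 0.61 (SE), and 2 hairy sums had no count. Cntn5 went from 24.6 ± 12.4 to 1.96 ± 1.67 CPM, a log2 change of -3.69 ± 0.51. The protocadherin gene Pcdh17 went from 120.2 ± 18.3 to 40.04 ± 18.4 CPM (-1.69 ± 0.22). In the other direction Mpped2, which encodes a metallophosphoesterase, went from 20 ± 12.3 to 73.8 ± 32.6 CPM (1.92 ± 0.22), and Zfp521 from 16.9 ± 7.36 to 67.04 ± 36.9 (1.86 ± 0.25).

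In all, 12 of 12852 genes passed the test, 5 higher and 7 lower in hairy skin, each in the same direction in 7 of 7 litters (edgeR quasi-likelihood with litter as a block, Benjamini-Hochberg adjusted p from 0.0422 to 0.0483). The other genes that rose were Cpne3, a copine gene, by 1.76 ± 0.22, the tubulin polyglutamylase gene Ttll5 by 1.32 ± 0.18 and the tetraspanin gene Tspan14 by 1.12 ± 0.14. The other genes that fell were Cxxc5 (-1.73 ± 0.25), Racgap1, a gene with a role in cytokinesis (-1.50 ± 0.20), Tmem47 (-1.26 ± 0.18) and the microtubule-associated Map7d2 (-1.14 ± 0.15). Uts2b lies on chromosome 16 at 27353322 to 27370239, Cntn5 on chromosome 9 at 9660891 to 10904775 and Mpped2 on chromosome 2 at 106693269 to 106868356 in mm10, and each is annotated as protein coding. Without a litter the count was 15 (C_D), 2 (E_F_G), 7 (H), 1 (L, Uts2b) and 0 (K, O and P_Q). In those last 3 fits edgeR found 1045, 1066 and 930 genes at an unadjusted p under 0.05, against 1277 with all litters, where DESeq2 called 337 genes and voomLmFit 1.2e+02.

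**Figure D2:**
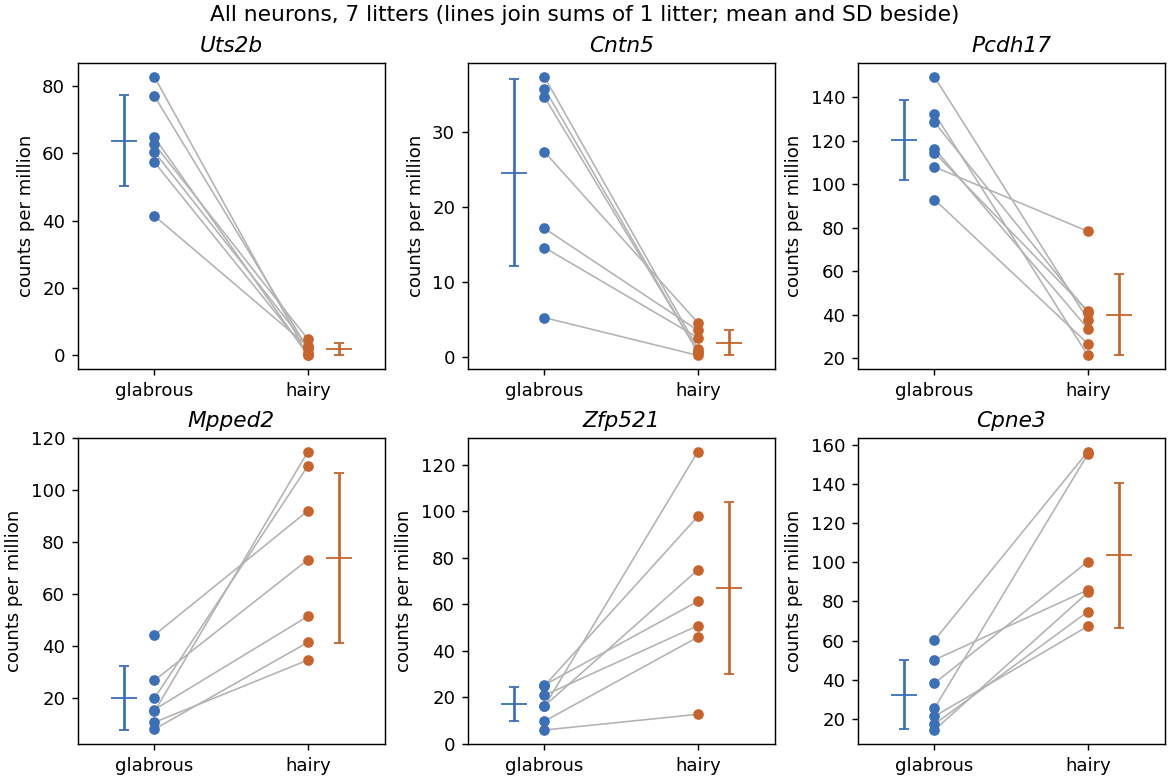
CPM (y axis) of 6 genes in sums of glabrous-skin and hairy-skin cells, where points are litters (n = 7), lines join the same litter, and bars beside them show mean and SD. Uts2b averaged 63.7 in glabrous and 1.85 in hairy sums, and Mpped2 20 and 73.8.

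Within plates the 12 genes kept their direction. Uts2b had a log2 change of -4.50 within plate 1 (3 litters) and -5.80 within plate 2 (4 litters), and Cntn5 -4.23 and -3.39. edgeR called 0 genes within either plate, with 521 genes at an unadjusted p under 0.05 in plate 1 and 1439 in plate 2. Sums were also made per litter, skin type and cluster (59 sums of 9 litters), with the cluster in the model, so several sums of the same litter and skin type entered as separate units. There Uts2b (-4.47 ± 0.56) and Cntn5 (-2.38 ± 0.48) passed the edgeR test, and the other 10 genes kept their sign but did not pass, with a median absolute change of 0.53 against 1.60 in the 7 litters without the cluster. With each litter and skin type as a random block in the same model, Uts2b (-3.72 ± 0.60) and Cntn5 (-2.52 ± 0.45) passed by voomLmFit and the other 10 did not. With at least 1 cell per sum, which gives 9 litters with 1 sum of each skin type, only Uts2b passed edgeR (-5.13), and Cntn5 had a change of -3.24. Without the C-fibre-like cells edgeR called 0 genes, with 709 at an unadjusted p under 0.05. There Uts2b had a change of -4.78 and Cntn5 of -3.28, whereas Zfp521, a marker of that class, had -0.34. Myelinating Schwann cell markers stood 0.90 higher (log2) in hairy cells, in 6 of 7 litters, with an exact two-sided sign-flip p of 0.125 (adjusted p = 0.844). With the level of non-neuronal markers in the model the 12 genes had a median absolute change of 1.68 against 1.71 and edgeR called 0 genes, with 1620 at an unadjusted p under 0.05.

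**Figure D3:**
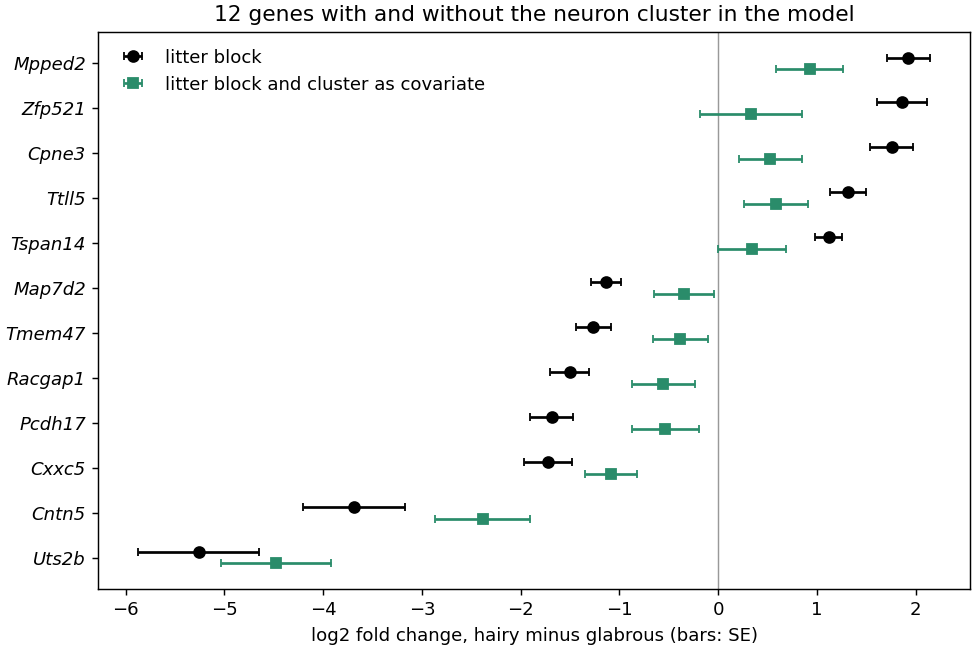
Log2 fold change, hairy minus glabrous (x axis, bars show SE), of the 12 genes that passed over all neurons (y axis), with litter as the block (7 litters) and with cluster added as a covariate. The fit with the cluster also used other units, 59 sums per cluster of 9 litters. Uts2b moved from -5.26 to -4.47 and Cntn5 from -3.69 to -2.38, and the other 10 genes had a median absolute change of 0.53 with the cluster in the model.

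None of the 14 genes of touch and BMP signalling fixed beforehand passed in the comparison over all neurons. The log2 change was -1.65 ± 0.36 for Ntrk3 (edgeR adjusted p = 0.170, lower in 6 of 7 litters), -2.84 ± 0.67 for the calcium-binding parvalbumin gene Pvalb (adjusted p = 0.198, 7 of 7) and -1.03 ± 0.38 for Nefh (adjusted p = 0.422, 7 of 7). Over 25 alternatives Ntrk3 passed in 5, Pvalb in 4 and Nefh in 1, and each kept its sign in all 25. It was -0.34 for Ntrk2, 0.40 for Ret, 0.44 for the mechanically gated channel gene Piezo2, -1.23 for Calca, -0.80 for Th and 0.26 for Mrgprd. Among BMP receptor and effector genes it was 0.26 for Bmpr1a, -1.13 for Bmpr1b, -0.35 for Bmpr2, -0.11 for Acvr1 and 0.52 for Smad1. Cdh12, a cadherin gene (-3.46 ± 0.51, adjusted p = 0.0534), and Tafa4 (4.30 ± 0.66, adjusted p = 0.0709) missed the threshold with 7 of 7 litters in the same direction.

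Of 24 gene lists tested over all neurons, 2 passed camera with its preset correlation. Markers of C-fibre low-threshold mechanoreceptors rose as a list (5 of 7 measured, 4 positive, median log2 change 1.86, limma camera adjusted p = 1.2e-05). That call was lost with an estimated correlation (adjusted p = 0.409). Of its members 1 passed over all genes and 4 when adjusted over the list alone: Tafa4, Zfp521, the purinergic receptor gene P2ry1 (1.53) and the cadherin gene Cdh9 (2.27). Neurofilament and node of Ranvier genes fell as a list (15 of 15 measured, 14 of them negative, median -0.36, camera adjusted p = 0.000163). This call too was lost with an estimated correlation (adjusted p = 0.409), and 0 members passed over all genes or adjusted over the list alone by edgeR, with 7 at an unadjusted p under 0.05. Its members with the smallest p were Tubb3, a neuronal tubulin gene (-0.35), Nefh (-1.03), Cntn1 (-0.63) and Nfasc (-1.05). This comparison did not hold the mix of clusters fixed, and the median of Nefh was 169 CPM in the C-fibre cluster 6. Within A-fibre low-threshold mechanoreceptor-like neurons alone the same list did not pass (15 measured, 8 positive, median 0.00075, camera adjusted p = 0.753).

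The remaining 22 lists had camera adjusted p between 0.222 and 0.936, but several held members that moved in both directions. Cadherins and contactins were the list with 0.222, and 6 of 23 measured members passed when adjusted over the list alone. Cdh9 was higher in hairy skin, and Cdh12, Cntn3 (-1.70), Cntn4 (-1.69), Cntn5 and Cntnap2 (-1.63) were lower. The fry test was also run on all 24 lists. For change in 1 direction 0 lists passed it, with adjusted p of 0.0731 for the C-fibre markers and 0.129 for the neurofilament list, which had passed camera. For change in either direction 3 lists passed: cadherins and contactins (fry adjusted p = 0.000444), mechanically gated and touch-related channels (0.000604) and C-fibre markers (0.0291). Adjusted over the list alone, 4 of 12 members of the neurotrophin and GDNF receptor list passed. Gfra2 (2.27) and the cytokine receptor gene Lifr (0.64), which the list also holds, were higher, and Ntrk3 (-1.65) and Gfra1 (-1.28) lower. The same was true of 2 of 11 members of the list of mechanically gated and touch-related channels, the acid-sensing channel genes Asic2 (0.68) and Asic3 (-1.74). It held for 3 of 23 potassium channels, Kcna4 (1.34), Kcnc2 (3.46) and Kcnab2 (-0.55), and for 3 of 23 sensory transcription factors, Runx1 (2.72), Prrxl1 (1.02) and Pou4f3 (-2.24). In the marker lists it held for Ntrk3 and Gfra2 of the A-fibre list, Pvalb of the proprioceptors, Gfra1 of the non-peptidergic nociceptors and Pmp22 (0.81) of the Schwann cells. BMP and TGF-beta genes (22 of 26 measured) had a median of -0.02 and an adjusted p of 0.906, and 0 members passed by edgeR adjusted over the list alone, with 2 at an unadjusted p under 0.05. In the lists of peptidergic nociceptor, fibroblast, axon injury, BMP and TGF-beta, neurotrophin and GDNF receptor and sensory transcription factor genes the median and the test differed in sign. In those of potassium channel and immediate early genes the mean and the test did.

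Within A-fibre low-threshold mechanoreceptor-like neurons, hairy-skin cells had more Calb1, the gene of the calcium buffer calbindin, and again less Uts2b. Calb1 averaged 96.2 ± 57.3 CPM in glabrous and 591 ± 464 in hairy sums (SD, n = 5 litters), a log2 change of 2.57 ± 0.21 (SE). Uts2b went from 82.5 ± 20.4 to 2.21 ± 3.03 CPM (-5.72 ± 0.76), with no count in 3 hairy sums. Aldoc, the gene of the glycolytic enzyme aldolase C, rose by 1.51 ± 0.20 and Erich3 by 2.62 ± 0.36. The protocadherin gene Pcdh19 changed by -3.54 ± 0.43 and Kcnip4, which encodes a potassium channel-interacting protein, by -2.81 ± 0.35.

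These 6 genes passed of 10605 tested, 3 higher and 3 lower in hairy skin and each in the same direction in 5 of 5 litters (edgeR quasi-likelihood, adjusted p = 0.00251 for Calb1 and 0.0361 to 0.0410 for the others). Calb1 lies on chromosome 4 at 15881264 to 15908064 in mm10. The next genes did not pass: Ntsr2 (-1.95 ± 0.28, edgeR adjusted p = 0.0630), S100a6 (-2.34), Cpne4 (-3.25) and Rgs17 (1.80). Nor did Ntrk2 (-0.36), Ret (0.84), Ntrk3 (-1.51), Nefh (-0.04), Piezo2 (0.65), Pvalb (-2.28), Bmpr1a (0.32), Bmpr2 (0.03), Acvr1 (-0.79) and Smad1 (0.24). In this class 8 of 9 hairy cells were in cluster 3, whereas the 42 glabrous cells spread over clusters 3 (11), 5 (17) and 7 (14). With the cluster in the model (16 sums of 5 litters) edgeR called 4 genes, of which Erich3 (2.66), Pcdh19 (-3.76) and Uts2b (-6.00) were shared with the 6, and all 6 kept their sign, Calb1 with 3.02. With each litter and skin type as a random block in that model, voomLmFit called 0 genes, with 726 at an unadjusted p under 0.05, and all 6 again kept their sign, Calb1 with 2.75. Within plate 1 (3 litters) and plate 2 (2 litters) edgeR called 0 genes, with 519 and 797 at an unadjusted p under 0.05. Calb1 had a change of 2.49 in plate 1 and 3.64 in plate 2.

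The sums of this comparison hold as few as 1 cell, a minimum set after the data had been seen. The planned minimum of 2 left 2 litters, where edgeR called 0 genes with 773 at an unadjusted p under 0.05. Without a litter the count was 20 (C_D), 1 (E_F_G), 3 (K), 1 (P_Q) and 0 (H, with 462 at an unadjusted p under 0.05), and with all 5 litters DESeq2 called 76 and voomLmFit 3.

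**Figure D4:**
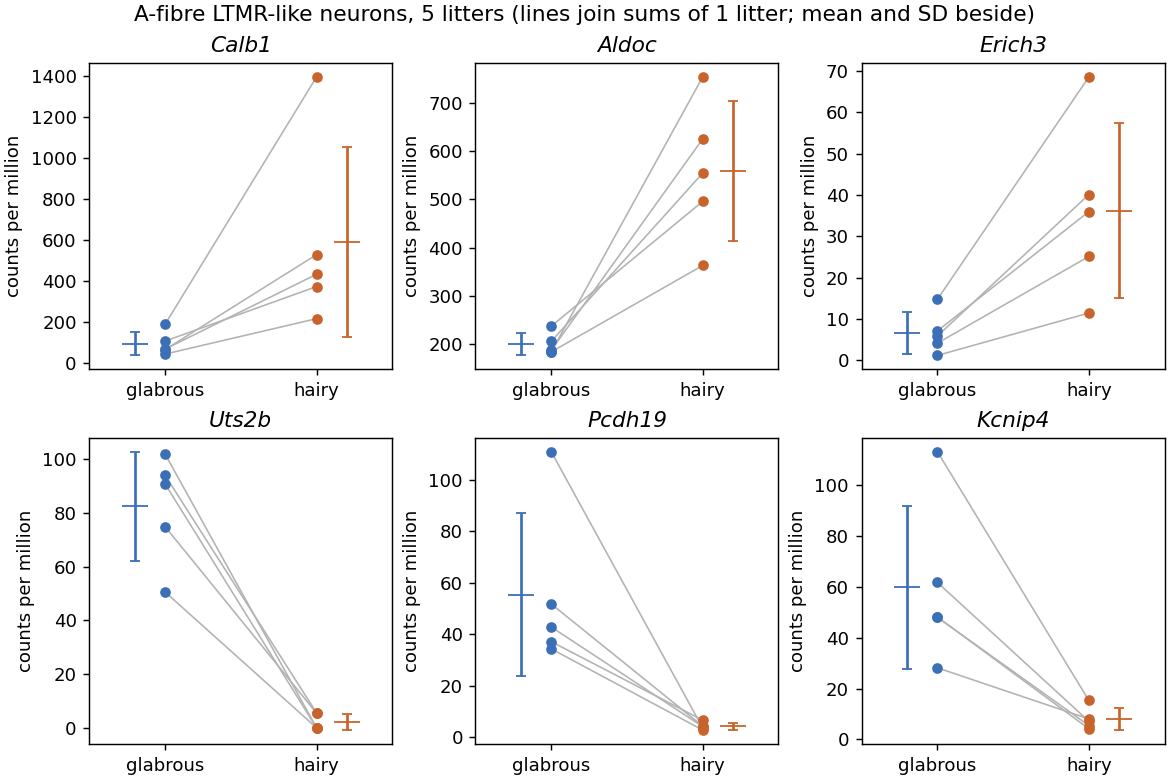
CPM (y axis) of the 6 genes that passed in A-fibre low-threshold mechanoreceptor-like neurons, in sums of glabrous-skin and hairy-skin cells, where points are litters (n = 5), lines join the same litter, and bars beside them show mean and SD. Calb1 averaged 96.2 in glabrous and 591 in hairy sums, and Uts2b 82.5 and 2.21.

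In the same neurons 8 of 23 lists passed camera with its preset correlation and 0 passed with an estimated one. By fry for change in 1 direction 3 passed, which were axon guidance receptors (adjusted p = 0.0114, camera 0.0820), cadherins and contactins and non-peptidergic nociceptor genes (both 0.0420). For change in either direction 4 passed fry: A-fibre markers and cadherins and contactins (both 0.00214), and mechanically gated and touch-related channels and axon injury genes (both 0.0362). Potassium channel genes rose as a list (21 measured, 15 positive, median 0.23, limma camera adjusted p = 0.0409, and adjusted p = 0.274 with an estimated correlation), led by Kcna4 (1.82) and Kcnd3 (1.59). Genes of synaptic glutamate release rose (17 measured, 12 positive, median 0.17, camera adjusted p = 0.0245, and adjusted p = 0.274 with an estimated correlation), but 0 members passed by edgeR over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05 (Unc13a, 0.64). Mitochondrially encoded genes rose (13 measured, 12 positive, median 0.21, camera adjusted p = 0.0135, and adjusted p = 0.514 with an estimated correlation). Of its members 0 passed by edgeR adjusted over the list alone, with 0 at an unadjusted p under 0.05. Without litter E_F_G the direction of that list turned and it did not pass, and over the alternatives its adjusted p ran from 2.89e-05 to 0.784. Cadherins and contactins fell (19 measured, 6 positive, median -0.33, camera adjusted p = 0.0135, and adjusted p = 0.254 with an estimated correlation). Of these 4 passed adjusted over the list alone: Cntn3 (-4.21), Cdh12 (-2.36) and Cntnap2 (-0.96) lower and Cntnap4 (3.71) higher. Axon injury genes fell (6 measured, 0 positive, median -0.61, camera adjusted p = 0.00544, and adjusted p = 0.254 with an estimated correlation), and the growth cone gene Gap43 (-0.89) passed over the list alone. Non-peptidergic nociceptor genes fell (4 measured, 1 positive, median -0.86, camera adjusted p = 0.0127, and adjusted p = 0.254 with an estimated correlation), among them P2rx3 (-0.73) and Gfra1 (-0.99).

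Markers of 2 other cell types were lower in these hairy-skin sums. Satellite glia markers fell as a list (6 measured, 0 positive, median -0.79, camera adjusted p = 0.00544, and adjusted p = 0.274 with an estimated correlation), with Apoe at -0.99, and 0 members passed by edgeR adjusted over the list alone, with 1 at an unadjusted p under 0.05. Fibroblast markers fell (4 measured, 1 positive, median -1.23, camera adjusted p = 0.0204, and adjusted p = 0.320 with an estimated correlation), with Col1a2 at -1.39 and Col3a1 at -1.17. The other 15 lists had camera adjusted p between 0.0709, for BMP and TGF-beta genes (17 of 26 measured, median -0.29), and 0.985, for mechanically gated and touch-related channels. Adjusted over the list alone, Piezo2 passed in the latter, Id2 (-1.45) in the BMP list, and Calb1, Gfra2 (1.76), Shox2 (1.77), Cadps2 (0.73) and Ntrk3 in the A-fibre marker list. So did Scn4b in the sodium channel list and Pvalb in the proprioceptor list, both lower in hairy skin. Ntrk3 and Gfra2 passed in the neurotrophin and GDNF receptor list as well. Without litter E_F_G 3 lists passed.

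Peptidergic nociceptor-like neurons showed no gene that differed between the skin types by edgeR, in 4 litters. Of 10312 genes 0 passed, with 468 at an unadjusted p under 0.05, and DESeq2 called 21. The smallest p-values belonged to Cdh12, with a log2 change of -2.34 ± 0.34, Gm12953, with -1.71 ± 0.30, Zcchc12, with 3.33 ± 0.59, and Uts2b, with -3.17 ± 0.58, each in 4 of 4 litters and each at an edgeR adjusted p of 0.966. These sums again held as few as 1 cell.

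Comparisons within single clusters were added after the data had been seen, where at least 3 litters held both skin types. The sums of these comparisons again held as few as 1 cell. In cluster 3, of A-fibre type, the acid-sensing channel gene Asic2 went from 10.9 ± 2.00 to 97.7 ± 8.91 CPM (SD, n = 4 litters), a log2 change of 3.18 ± 0.34. It was the only gene of 9897 that passed there (edgeR adjusted p = 0.0419, higher in 4 of 4 litters), and Uts2b had a change of -6.46 ± 0.79 (adjusted p = 0.0553, lower in 4 of 4). Without any 1 of the 4 litters edgeR called 0 genes in cluster 3, with 365 to 639 at an unadjusted p under 0.05, whereas voomLmFit called 6 with all of them. In clusters 1 and 4 edgeR and voomLmFit called 0 genes, with 483 and 156 at an unadjusted p under 0.05 by edgeR. Without litter K the neuropeptide gene Tac1 passed in cluster 1.

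Age was compared mainly in glabrous neurons, 2 litters at postnatal day 4 against 7 at postnatal day 5, and age shares its litters with plate and cDNA batch. Of 15185 genes 0 passed edgeR, with 422 at an unadjusted p under 0.05. In the same glabrous neurons DESeq2 called 3, which were Kcnip2, Ldb2 and Pigz. The edgeR log2 change, day 5 minus day 4, was 3.36 ± 0.89 for the potassium channel-interacting protein gene Kcnip2, -0.60 ± 0.13 for Pigz and 2.60 ± 0.57 for the zinc-finger gene Zkscan2. Among litters with cells on plate 2, edgeR called 0 genes with 758 at an unadjusted p under 0.05, and without litter E_F_G it called 1 (Chodl). In hairy neurons (8 litters) edgeR called 0 of 14063 genes, with 200 at an unadjusted p under 0.05. A test of whether the skin-type difference itself changed with age gave 0 of 12852 genes by edgeR, with 87 at an unadjusted p under 0.05. Its smallest p-values belonged to Ldb2 (-2.95 ± 0.46), Tmem45b (-6.14 ± 1.10) and Rasgrp1 (-3.07 ± 0.63), each at an adjusted p of 1.00.

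Hairy-skin cells had slightly fewer detected genes than glabrous-skin cells. The difference in median log10 number was -0.0138 ± 0.00905 (SD, n = 7 litters), lower in 7 of 7 litters, with an exact two-sided sign-flip p of 0.0156, the smallest possible. With means in place of medians it was -0.00091. Total counts differed by -0.00901 ± 0.0654 log10 units (exact p = 0.672). The mitochondrial share averaged 3.70% in hairy and 3.30% in glabrous cells, and none of 9 such measures, among them markers of glia, Schwann cells, fibroblasts, endothelium, macrophages and red blood cells, passed the exact sign-flip test, with adjusted p from 0.844 to 0.969.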

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

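The tests of the C-fibre class in this part were chosen after the result was seen. Of about 1.0e+02 groups of 4 to 10 litters, 10 had a highest or lowest litter whose gap to its nearest neighbour, as a share of the group's range, was above Dixon's 95% limit, and chance gives about 1 in 20 groups. Values of genes are log2(CPM + 1) of a litter's sum.

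Over all neurons, glabrous Ret was 4.752 in litter L, where the median of the other litters was 8.343. Glabrous Nefh was 9.421 in litter H, with a median of 10.58 in the others, and glabrous Th was 1.042 in litter L, with a median of 2.614 in the others. In A-fibre low-threshold mechanoreceptor-like neurons, 4 of the 5 separated values were in litter C_D, where the glabrous sum held 1 cell and the hairy sum 2. There hairy Cpne4 was 5.062 against a median of 2.191 in the other litters, glabrous Ntrk2 was 3.738 against 7.897, hairy Ntrk2 was 8.148 against 6.634, and hairy Acvr1 was 4.293 against 2.39. Glabrous Cpne4 was 4.469 in litter K, against a median of 6.335. Without litter C_D edgeR called 20 genes in these neurons in place of 6, and the 6 were among the 20. The share of cluster 4 among glabrous cells was 57.14% in litter H (4 of 7 cells), with a median of 3.226% in the other litters.

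The cell labelled with both skin types was used in no comparison. It had Uts2b at 91.49 CPM (73 counts), above the 3.76 that a count of 0 allows, whereas hairy sums averaged 1.85 and glabrous sums 63.7.

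The share of C-fibre low-threshold mechanoreceptor-like cells among glabrous cells was 33.33% in litter L, which is 1 of 3 cells, and 0 in the other 6 paired litters. The class was more frequent in hairy than in glabrous skin in 5 of 7 litters (21.2 points, exact two-sided sign-flip p = 0.0625, the smallest possible with 2 litters at 0), and its cluster carried more Schwann cell and fibroblast markers than most. Each paired litter except K lay on 1 plate, so the pairing already holds plate fixed there. The difference was 32.08 points within plate 2 (4 of 4 litters) and 6.67 points within plate 1 (1 of 3 litters positive). These values come from the same litters as the main result, so they are no separate test of an uneven spread of skin types over plates. Clustering without 779 genes that follow non-neuronal markers left a matching cluster with a difference of 20.24 points, which argues against RNA from non-neuronal cells shaping the cluster. Clustering without 391 genes whose mean differed in the same direction in all 7 litters by more than 0.5 on average (log2, not a test) left 19.15 points in a matching cluster of 21 cells, which held all 17 of the class but no longer met the rule for its name. There 5 litters were higher and 1 was lower in hairy skin. This argues against clustering on such genes as the source of the group of cells, not of its name. A difference in which neurons serve the skin types, and a difference in how neurons were labelled or picked, stay open and were not tested.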

How the results depend on the processing

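Plate 1 alone, plate 2 alone for class shares, sums without C-fibre-like cells, the cluster (with or without a random block) or non-neuronal markers as a covariate, clustering without the genes with the same direction in all litters or that follow non-neuronal markers, the minimum of 10000 genes, thinning, centring on cluster medians, differences within litter and cluster and all tests within clusters were chosen after seeing the data. So was the minimum of 1 cell per sum in the reported A-fibre and peptidergic comparisons, and the other choices were made before the data were examined. For results named below that changed, the cause was not tested unless it is given. Among values of named genes over all alternatives, 1009 kept their direction and side of the threshold, 48 passed where the reported value did not, 254 no longer passed and 55 turned in direction. Among gene lists these numbers were 64 kept, 29 no longer passing and 1 turned. Among the other results 158 kept, 55 counts or values moved, 14 turned, 3 passed where the reported value did not and 3 no longer passed.

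Over all neurons (12 genes) the count was 342 with no low-count filter, 337 by DESeq2, 73 with no litter block, 1 with at least 1 cell per sum, 21 with at least 3, 21 by limma on mean log2(CPM + 1), 1.2e+02 by voomLmFit, 98 with cells as units and 1 in day 5 litters. It was 0 in plate 2, 0 in plate 1, 0 without C-fibre-like cells, 5 with the cluster as covariate, 5 with the cluster and a random block for each litter and skin type (voomLmFit), 0 with non-neuronal markers as covariate, and 0 (without K) to 15 (without C_D) with a litter left out. It was 10 with RLE factors and 11 with at least 10000 genes. All 12 genes kept their sign in every alternative except Zfp521 without C-fibre-like cells (-0.34), where the cells of the class it marks had been left out. DESeq2 and the fit with no filter called all 12 among their genes, the fit with no block 10 and limma on means 4. Both cluster fits use 59 sums of 9 litters, and each shared 2 of its 5 genes with the 12.

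In A-fibre neurons (6 genes) the count was 186 with no low-count filter, 76 by DESeq2, 22 with no litter block, 0 with at least 2 cells (2 litters left), 3 by voomLmFit, 0 in day 5 litters, 0 in plate 2, 0 in plate 1, 0 with the cluster and a random block (voomLmFit, 726 at an unadjusted p under 0.05), and 0 (without H) to 20 (without C_D) with a litter left out. At least 3 cells left too few litters for a value. The minimum of 2000 genes removed 0 cells, so leaving it out changes nothing. All 6 genes kept their sign in every alternative run. In peptidergic neurons (0 genes) no filter gave 1.2e+02 and DESeq2 21. No filter gave 168 in cluster 1, 1.2e+02 in cluster 3, 16 in cluster 4 and 41 for the interaction with age. Cluster 3 (1 gene) gave 0 with no block, 6 by voomLmFit and 0 with any litter left out. Leaving out a litter gave 0 to 1 in cluster 1 (1 without K). The age comparison (0 genes) gave 3 by DESeq2, and 0 to 1 with a litter left out (1 without E_F_G).

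With no litter block, cells pooled over litters gave class differences that passed Fisher's exact test where the litter test did not (for the C-fibre class and cluster 2 it could not), -20.4 points for A-fibre, 28.2 for C-fibre and -19.2 for cluster 2, which treats cells as replicates. The C-fibre difference kept its sign in every alternative that gave a value, and was 10.1 with at least 1 cell per litter. The A-fibre difference turned to 3.14 with at least 1 cell per litter and 21.01 in plate 1, and ran from -26.5 (without C_D) to -0.84 (without L) with a litter left out. The cluster 4 difference turned to -0.69 with at least 1 cell, -0.43 pooled and -1.90 in plate 2, and ran from -2.46 to 6.46 with a litter left out. The peptidergic difference turned to -10.4 with 1000 variable genes, -7.72 with 3000 and -15.5 in plate 1, and ran from -0.89 to 10.4 with a litter left out. At Leiden resolution 0.5 no cluster met the rule for the C-fibre name, so there is no value. The cluster that overlapped most differed by 30.9 points, but it held 35 cells, of which 16 were among the 17 of the class.

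The difference in detected genes was -0.00091 by means, -0.00967 after thinning and -0.00278 after centring on cluster medians, and turned to 0.05117 among cells of the same litter and cluster, and none of these passed. Centring partly sets its own outcome, since some clusters hold cells of 1 skin type. The difference in total counts ran from -0.03007 (without L) to 0.00566 (without K). With an estimated correlation 0 lists passed over all neurons and 0 in A-fibre neurons. In A-fibre neurons 1 list passed with no block and 3 (without E_F_G) to 8 with a litter left out, and the adjusted p of the mitochondrial list ran from 2.89e-05 (without P_Q) to 0.784 (without E_F_G, with the direction turned).

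Of the fixed genes, 3 passed in some alternatives. Over all neurons Ntrk3 passed with no filter, by DESeq2, with no block, by voomLmFit and without C_D (-1.97), Pvalb with no filter, by DESeq2 (-3.09), by limma on means (-2.66) and with cells as units, and Nefh with no filter (-1.07). In A-fibre neurons Ntrk3 passed with no filter and by DESeq2 (-1.52), and Pvalb with no filter (-2.36). The fixed genes below passed in neither the reported test nor the alternative where they turned. In A-fibre neurons Bmpr1a was -0.14 with at least 2 cells. Bmpr2 was -0.39 with at least 2 cells, -0.028 with no filter, -0.12 with no block, -0.35 in plate 2, -0.068 with cells as units, -0.042 with the cluster, -0.052 with the cluster and a random block, -0.073 by voomLmFit, and -0.17 to 0.18 with a litter left out. Nefh was 0.41 with at least 2 cells, 0.034 with no block, 0.57 in plate 2, 0.0165 with cells as units, 0.019 by voomLmFit, and -0.22 to 0.11 with a litter left out. Ntrk2 was 0.79 by limma on means, 0.17 in day 5 litters and in plate 1, which hold the same 3 litters, 0.75 with the cluster and 0.48 with the cluster and a random block. Ret was -0.24 with the cluster and -0.70 with the cluster and a random block. Smad1 was -0.30 in day 5 litters and plate 1, and -0.024 to 0.53 with a litter left out. Over all neurons Acvr1 was 0.15 in day 5 litters, 0.057 in plate 1, and -0.29 to 0.020 with a litter left out. Bmpr1a was -0.024 in plate 1 and Bmpr2 0.095 with the cluster and 0.23 with the cluster and a random block. Calca was 0.70 with at least 3 cells, 1.72 in plate 2, 0.85 with cells as units, 0.27 with the cluster and 0.19 with the cluster and a random block. Mrgprd was -0.45 with at least 10000 genes, -0.97 with no block, -0.37 in day 5 litters, -0.049 in plate 1, -0.33 by voomLmFit, -0.15 with the cluster and a random block, and -0.21 to 0.99 with a litter left out. Ntrk2 was 0.48 by limma on means, and -0.98 to 0.31 with a litter left out. Piezo2 was -0.0023 with the cluster and -0.066 without C-fibre-like cells. Ret was -0.008 in plate 1, and -0.019 to 0.68 with a litter left out.

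Small changes are missed at this depth and number of litters, and neither was varied in the simulation: on simulated data edgeR recovered 33.3% of changes of 1 log2 unit over all neurons, 13.6% in A-fibre neurons and 4.2% between ages.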

Other observations

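The tests in this part were chosen after the results were seen, apart from the fit on day 5 litters, which was fixed before the data were examined, and the fit with non-neuronal markers, which was added after seeing the data but whose expected outcome was set before it was run.

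With sums per cluster and the cluster in the model, 3 genes passed edgeR over all neurons that had not passed in the 7 litters with 1 sum per skin type. Cdh12, a cadherin gene, had a log2 change of -2.11 ± 0.37 (SE). Zcchc12, which encodes a zinc-finger protein, had 2.87 ± 0.55 and Heatr5a 1.77 ± 0.32. That fit holds 59 sums of 9 litters, several of them from the same litter and skin type, so these calls cannot be put down to the cluster term alone. With each litter and skin type as a random block (voomLmFit), Cdh12 (-2.16 ± 0.44) and Heatr5a (1.62 ± 0.32) passed again, as did the protocadherin gene Pcdh19 (-2.18 ± 0.43), and Zcchc12 did not. Cdh12 and Zcchc12 were also among the 10 genes with the smallest p-values in peptidergic nociceptor-like neurons (-2.34 and 3.33, neither passing). The unnamed cluster 2 held 20 glabrous cells, no hairy cell and the cell with both labels, and expressed the serotonin receptor gene Htr3a (median 282 CPM, counts scaled to the library total) and the prostacyclin receptor gene Ptgir (114.3), as cluster 1 did (273 and 102.95). Its satellite glia markers had a summed median of 44.9 CPM against 1606 in cluster 1, and 18 of its 21 cells were on plate 1. In the day 5 litters alone the single gene that passed edgeR over all neurons was Ldb2, which encodes a LIM-domain-binding protein (2.26 ± 0.18). Its median was 525.6 CPM in the C-fibre cluster and 313 in cluster 4.

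The cell labelled with both skin types was in cluster 2, with 797882 counts and 14126 detected genes. It had Nefh at 2741, Ret at 1440, Ntrk3 at 266, Cntn5 at 18.8 and Mpped2 at 12.5 CPM, and no count of Ntrk2. Of the 6 cells under 10000 detected genes, hairy cell 37 had 41.2% mitochondrial counts, glabrous cell 69 had 50.3% and glabrous cell 73 had 24.7% haemoglobin counts. Without these 6 cells 11 of the 12 genes passed over all neurons.

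The 12 genes that differed over all neurons may partly reflect a different mix of neuron clusters in the skin types. With the cluster as a covariate, 2 genes, Uts2b and Cntn5, still passed (also with each litter and skin type as a random block, by voomLmFit). Of the other 10 genes 8 lay within 2 SE of 0, as a different mix would give. The split into 2 and 10 genes was made after the results were seen, so it is no separate test of a different mix. It shows only that for these 2 genes a change remained with the cluster in the model. The summed level of non-neuronal markers as the whole source is argued against for the 12 genes. With that level as a covariate, 0 of them lay within 2 SE of 0. That fit called 0 genes: the median absolute log2 change was 1.71 (median SE 0.218) before and 1.68 (0.225) after, and the extra term left 1 degree of freedom fewer. The 12 genes had been chosen for passing in the same sums. The level adds up satellite glia, Schwann cell and fibroblast markers, which differed by -0.33, 0.90 and -0.79 (log2, hairy minus glabrous). RNA from any 1 of these cell types therefore stays open. A difference in skin type within a cluster, and differences between the glabrous and hairy members of a cluster in subtype, stay open.

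Uts2b had a count in 12 of 45 hairy cells (26.7%) and 85 glabrous cells (81.7%). Per litter the share was 27.4% ± 21.2 (SD, n = 7) in hairy and 74.2% ± 21.2 in glabrous skin, lower in 7 of 7 litters, with an exact two-sided sign-flip p of 0.0156, the smallest possible, and with counts thinned to 1 total the difference was -50.0 points. The hypothesis that Uts2b is lower in every cluster that holds cells of both skin types was tested on the clusters with at least 3 cells of each, and the mean was lower in hairy cells in 5 of 5. These means pooled cells over litters. In cluster 8 none of the 7 paired litters held both skin types, and in cluster 6 only litter L did, so litter and plate were not held fixed there. In clusters 1, 3 and 8 the mean of Uts2b was 51.2, 79.4 and 43.1 CPM in glabrous and 6.18, 1.38 and 0.222 in hairy cells. In cluster 1 the level differed but hardly the share of cells with a count, 8 of 10 hairy (80%) and 19 of 22 glabrous (86.4%). In clusters 4 and 6, the latter of C-fibre type, the mean was near 0 in both skin types, at 1.26 and 0.946 CPM in glabrous and 0 and 0.209 in hairy cells, with a count in 4 of 12 and 1 of 3 glabrous cells. Uts2b may therefore be higher in glabrous-skin neurons of the peptidergic cluster 1 and the A-fibre cluster 3, with no such difference to see in clusters 4 and 6, as a hypothesis found and tested on the same cells. In cluster 8 the difference cannot be told apart from one between litters or plates.

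For the lower number of detected genes in hairy-skin cells (-0.0138 log10, 7 of 7 litters) no source could be named. Among cells of the same litter and cluster (13 pairs in 8 litters) the difference was 0.05117 (SE 0.05578), a spread too wide to decide on a different mix of neuron clusters. With counts thinned to 1 total it was -0.00967 (SE 0.00533), within 2 SE of 0 but more than 50% of its size before, so a difference in total counts per cell cannot be told apart from none in 7 litters.

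Skin types were also swapped within litters to count how often another split calls as many genes. Over all neurons 1 of 64 splits, the real one, gave as many as 12 genes, and the highest of the others gave 3. That is the smallest share that 64 splits can give, so it argues against chance but does not exclude it. In A-fibre neurons 1 of 16 splits gave as many as the real 6, with 0 as the highest of the others, and in cluster 3 it was 1 of 8 splits, with 1 gene against 0. In peptidergic neurons 8 of 8 splits gave as many as the real 0, with 1 as the highest of the others, in cluster 1 it was 8 of 8, with 2, and in cluster 4 it was 4 of 4, with 0. The splits in these 5 comparisons are too few for a share under 0.05.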
